A study of Homo sapiens with 204 samples.

How the data were processed

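Ribosomal proteins were knocked down one at a time in A549 lung adenocarcinoma cells with siRNA at 40 nM for 24 h, and non-targeting siRNA served as control. Per the labels' protocols, cells were treated with cycloheximide, which holds ribosomes on mRNA, and each lysate was divided into an aliquot for Ribo-seq, digested with nuclease, depleted of rRNA and selected for footprint length on a gel, and an aliquot for RNA-seq. The libraries analysed here are, per assay, 91 from knockdowns of 75 ribosomal proteins and 11 from controls.

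The deposited values are whole-number read counts per Ensembl gene, in 1 table per assay, over exons for RNA-seq and over coding sequences for Ribo-seq, per the file headers. They are not normalized and libraries are not pooled. Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 1.8.1, STAR 2.6.1 and the genome build GRCh38 were used; the counting program, its treatment of reads that map to several genes, strand settings and the annotation release are not given in the sources used here. Genes with near-identical copies or overlaps (histones, ribosomal proteins and their pseudogenes, HSPA1A and HSPA1B, read-through genes) are therefore uncertain. Columns were matched to samples by name (RPS15 RNA-seq despite a different sample number), and 0 with values stayed unmatched. Controls 21_1 and 21_2 are named after their columns, which show the group but not the title. Their RNA-seq and Ribo-seq columns were taken as 1 lysate by the shared name. No genome was used. Of 41379 gene identifiers in RNA-seq, 40811 had a symbol, and 224 had no counts; of 19217 in Ribo-seq, 19119 had a symbol and 12 no counts.

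Libraries per group were compared first. Over 71 pairs of libraries of one group, the chi-square statistic per degree of freedom was at least 3.47 in RNA-seq (median 44.8) and 3.71 in Ribo-seq (median 37.9), so no pair differed as little as sampling noise would give and all were counted as separate libraries. Depth is given with the data collected; floors for a count of 0 use 3 counts of the library total. Columns form 3 runs, with median totals of 41.4, 21.4 and 32.0 M counts in RNA-seq and 18.5, 24.3 and 29.7 M counts in Ribo-seq. Except for RPS16 and both run 3 controls, only run 1 has numbered titles. The title set was a term in each fit and the run an alternative chosen after the data were seen.

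Tests ran in R 4.3.3. Genes with at least 1 CPM in at least 11 libraries were kept, which left 15526 genes in RNA-seq (99.8% of counts) and 12793 in Ribo-seq, and 12480 in both for translation efficiency. Counts were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, title set as covariate), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were all knockdowns against control, large- against small-subunit knockdowns with controls as a further group for the spread, and each of the 16 targets with 2 libraries against the controls of its title set. The last used 1 fit with a mean per target, in which groups of at least 2 libraries set the dispersion. Translation efficiency was tested as the interaction of assay and group in 1 model over both assays. Because both assays came from the same lysate by protocol, limma 3.58.1 (trend) was also run on per-lysate log2 ratios of Ribo-seq to RNA-seq CPM (prior count 2), and its values stand beside the others as lysate-blocked. The lysate pairing was checked on deviations from the group means, where RNA-seq and Ribo-seq of 1 lysate had a median r of 0.262 and 72.1% of 43 pairs were over 0.1. SE are computed from the log2 fold change and the test statistic.

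The 28 gene lists, the tests, the covariates and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma) with a preset correlation of 0.01, and again with an estimated one, on log2 CPM (prior count 2) or per-lysate ratios, adjusted over all lists and comparisons. Named genes are, among those past the threshold with a mean CPM of at least 5 (in both assays for translation efficiency), the 8 with the largest positive and the 8 with the largest negative log2 fold change, the 3 members with the smallest p of each called list, and CDKN1A, MDM2, MYC and the targeted genes. For the 16 targets they are the 3 genes called higher and the 3 called lower in most of them, ties by mean size. Other genes are said to be named after their values were seen. Some genes that the rule takes, and some values of single targets, are not reported here.

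Ratios per library are log2 of CPM (TMM-scaled, pseudocount 0.5) to the mean of the controls of the same title set. The distance from control is the SD of these ratios over genes with a mean CPM of at least 10; list scores are means over members. Permutation tests used 100000 resamples, and all regroupings (an exact test) where a group has under 10 values. Correlations over the 75 targets are given with Pearson's r and Spearman's rho. Overlaps over the 16 targets are set beside the number for independent lists, unchanged groups simulated against shared simulated controls, and controls split between targets.

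These tests, and no others, were run on simulated counts with seeded changes at log2 1 or 2, counted among the changed genes that passed the filter. Against control, 98.0% at log2 1 and 100% at log2 2 were called in RNA-seq (15428 genes, 6 false calls), 94.8% and 97.9% in Ribo-seq (12740 genes, 12 false calls) and 90% and 98.9% in translation efficiency (12443 genes, 14 false calls). Between subunits they were 100% and 100% in RNA-seq (15446 genes, 16 false calls), 97.0% and 100% in Ribo-seq (12752 genes, 10 false calls) and 99.0% and 100% in translation efficiency (12456 genes, 17 false calls). For 2 RPS3 libraries against control in RNA-seq they were 43% and 91% (15458 genes, 5 false calls), so many changes at log2 1 go uncalled with 2 libraries. For the lysate-blocked test against control they were 76% and 99.0% (12446 genes, 5 false calls). Camera called the 1 planted list of 28 and none of the others.

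Other settings set in advance were DESeq2 1.42.0 size factors in place of TMM, the DESeq2 Wald test, no low-count filter or a stricter one of at least 10 counts, summed libraries per target, no title set term, each title set alone, a replicate block, leaving out each control or repeat, all 11 controls, the lysate block with prior count 2 or 0.5, a pseudocount of 5, a mean CPM of at least 50, library totals as scaling, the median absolute deviation, thinning to the shallowest library, Spearman correlation, medians of lists, averaged libraries, and setting targeted genes aside in the ribosomal protein lists. Chosen after the data were seen were the run of columns as a term, with and without the lysate block, controls of the same run, leaving out control 20_2 in the tests per target and of lists, and splitting the controls between targets. Exact tests for small groups, the use of the dispersion of the full fit in some alternatives per target and the number of random splits of the samples (40) were also set then. Targets with 1 library entered no test of their own.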

Results

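A549 cells, a human lung adenocarcinoma line with wild-type p53, were transfected with small interfering RNA (siRNA) against 75 ribosomal proteins one at a time, or with non-targeting siRNA as control, at 40 nM for 24 h. Of the targets, 44 belong to the large and 31 to the small ribosomal subunit. Each lysate was divided between RNA-seq, which measures mRNA amounts, and Ribo-seq, which sequences the short mRNA fragments that ribosomes protect from nuclease and so measures where ribosomes sit. Each assay has 91 libraries from knockdowns and 11 from controls; 16 targets have 2 libraries and 59 have 1. The design asks how the loss of each ribosomal protein changes mRNA amounts and their translation relative to control cells. The count tables hold whole reads per gene, over exons for RNA-seq and over coding sequences for Ribo-seq. RNA-seq totals ran from 18.8 to 63.6 M counts (mega; median 27.8) and Ribo-seq totals from 7.77 to 57.2 M counts (median 23.8). A count of 0 in the shallowest library allows up to 0.160 CPM (counts scaled to a common library total) in RNA-seq and 0.386 CPM in Ribo-seq. These limits, 3 counts, cover counting error only. The titles form 2 sets, 38 libraries per assay whose titles carry a sample or replicate number (6 controls, 4 large- and 12 small-subunit targets) and 64 without one, called unnumbered here (5 controls, 40 large- and 19 small-subunit targets). RNA-seq was deeper in the numbered set (median 41.02 against 22.1 M) and Ribo-seq shallower (18.97 against 24.9 M), and each comparison below held the set as a term. The series description calls the repeats of 16 targets biological without saying whether they came from separate cultures, and knockdown and control cells are one line, so p-values measure the spread between these libraries, which may be partly technical.

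The targeted mRNA was reduced in every knockdown. In RNA-seq all 91 knockdown libraries had less of the targeted mRNA than any of the 11 controls, with a median log2 ratio of -4.56 over the 75 targets (range -5.99 to -2.66) and a median of 4.06% of the control level left (1.54 to 15.7%). Among the 16 targets with 2 libraries, the fitted log2 fold change ran from -5.74 ± 0.26 (SE) for RPS3, a small-subunit protein at the mRNA entry site, to -2.80 ± 0.13 for RPS15A, with adjusted p = 2.69e-16 and 5.35e-15 (edgeR quasi-likelihood test, Benjamini-Hochberg). Footprints on the targeted mRNA were also lower, with a median log2 ratio of -4.05, and lay below all controls in 85 of 91 libraries. The other 6 libraries were both RPS26 libraries (0 and 4 footprint counts against a control median of 3) and those of RPL39, RPL7, RPL9 and RPS28. For RPS28 the footprint count was 41 against a control median of 12, while its mRNA was at 2.51% of control. In the controls 8 targets had under 100 footprint counts, so their footprint change is imprecise, though called for RPL21 (-3.95 ± 0.82).

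**Figure D1:**
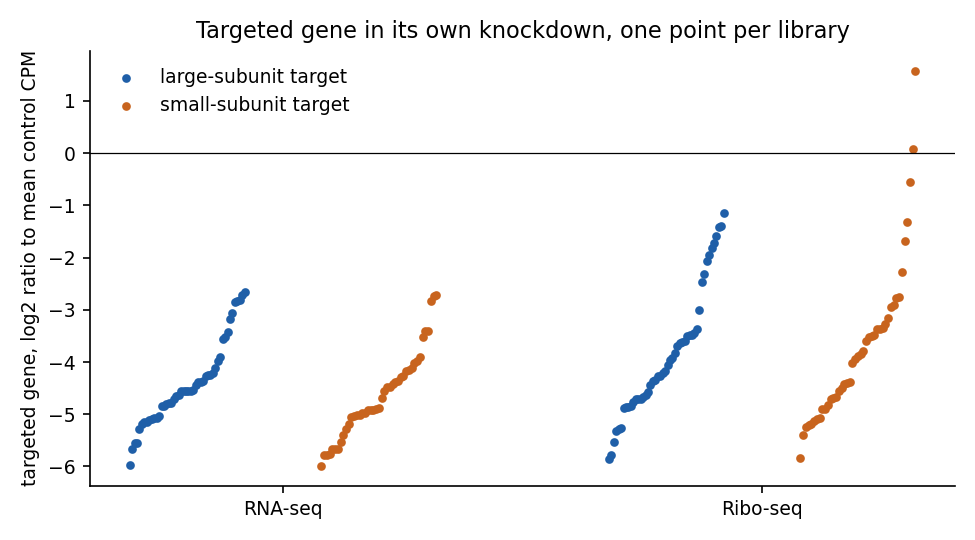
Log2 ratio of the targeted gene's CPM to the mean CPM of the controls of the same title set, 1 point per knockdown library, sorted within large-subunit (blue) and small-subunit (orange) targets for RNA-seq and Ribo-seq. All RNA-seq points lie between -5.99 and -2.66, and the Ribo-seq points reach up to 1.58, for RPS28.

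Libraries of the same target shared their own deviations from the average knockdown. Over genes, the deviations of the 16 pairs of libraries of one target correlated with a mean Pearson r of 0.858 ± 0.146 (SD, n = 16) in RNA-seq, 0.820 ± 0.0929 in Ribo-seq and 0.617 ± 0.193 for translation efficiency, against -0.0579, -0.0573 and -0.0511 for libraries of different targets. These r are across genes, which are not independent replicates. The partner library gave the highest r for 16 of 16 targets in both assays and for 11 of 16 in translation efficiency (one-sided permutation p = 1e-05 each, the smallest they can give). The overall size of the response, as the SD over genes of the log2 ratio to control, was 0.457 ± 0.103 (SD) for the 44 large-subunit targets and 0.437 ± 0.0753 for the 31 small-subunit targets in RNA-seq (two-sided permutation p = 0.357). The difference was 0.0410 (exact permutation p = 0.421) in the numbered titles and 0.0462 (permutation p = 0.0657) in the others. In Ribo-seq it was 0.541 ± 0.106 and 0.496 ± 0.0826 (permutation p = 0.0539), with differences of 0.0667 (exact permutation p = 0.232) and 0.0423 (permutation p = 0.132) within the sets. Neither difference passed 0.05; the Ribo-seq difference did with all 11 controls (0.0530), with a mean CPM of at least 50 (0.0540) or with libraries thinned to one depth (0.0449). As median absolute deviations the differences were -0.0149 in RNA-seq and 0.000319 in Ribo-seq (permutation p = 0.985). The control medians were 0.459 in RNA-seq and 0.337 in Ribo-seq in the numbered titles, and 0.184 and 0.261 in the others. In RNA-seq 0 of the 16 numbered targets (means of 0.531 and 0.490 for large and small) and 49 of the 59 others lay above all controls of their set. One control library, 20_2, stood at 0.983 in RNA-seq, above all 75 targets, and at 0.220 in Ribo-seq. Targets whose own mRNA fell further had larger RNA-seq responses (Pearson r = -0.338, permutation p = 0.00293; Spearman rho = -0.338, permutation p = 0.00290; adjusted p = 0.00439 and 0.00435 over 12 relations; r = -0.289 without the 2 most distant targets; n = 75). Within the 16 targets of the numbered titles r was -0.0431 (permutation p = 0.875) and within the 59 others -0.425 (permutation p = 0.000690) (whether the sets differ was not tested). In Ribo-seq r was -0.184 (permutation p = 0.113) and rho -0.294 (permutation p = 0.0103), with adjusted p = 0.150 and 0.0137.

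Averaged over all knockdowns, most mRNAs of p53 target genes rose and most for DNA replication, histones and mitosis fell, but the list calls were lost with an estimated correlation. BTG2, an antiproliferative gene induced by p53, rose by 2.47 ± 0.41 (log2 fold change ± SE, 91 knockdown and 11 control libraries), from 14.4 ± 3.39 CPM (SD) in controls to 87.2 ± 65.6 CPM in knockdowns. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 1.54 ± 0.34 and MDM2, the ubiquitin ligase that restrains p53, by 1.37 ± 0.29 (adjusted p = 0.000274 and 0.000131, edgeR quasi-likelihood test, Benjamini-Hochberg). FAM111B, a protease of proliferating cells, fell by 1.64 ± 0.36 and E2F2, a transcription factor of S phase entry, by 1.35 ± 0.33. In all, 2074 of 15526 genes tested rose and 2671 fell, or 2256 and 2323 without control 20_2.

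Of the 35 p53 target genes, 27 rose and 8 were not called (29 rose adjusted over the list alone). The examples include the ferredoxin reductase FDXR (1.86 ± 0.30), the DNA damage sensor XPC (1.47 ± 0.16), the pro-apoptotic BBC3 (1.37 ± 0.20) and DDB2 (0.81 ± 0.12). Camera called the list higher with adjusted p = 1.53e-16, and with adjusted p = 0.218 with an estimated correlation. Of 44 DNA replication and G1/S genes, 34 fell and 10 were not called (38 fell adjusted over the list alone). They include cyclin E2 CCNE2 (-1.21 ± 0.27), the flap endonuclease FEN1 (-0.99 ± 0.20) and the helicase subunit MCM7 (-0.84 ± 0.18), and the list had adjusted p = 1.66e-12, or adjusted p = 0.452 with an estimated correlation. Of 37 replication-dependent histone genes measured, 34 fell (35 adjusted over the list alone), among them H2BC17 (-0.97 ± 0.23), H3C1 (-0.95 ± 0.20) and H4C13 (-0.89 ± 0.19). Their near-identical copies can share reads, so single histone values are uncertain. The list had adjusted p = 7.80e-13, or adjusted p = 0.449 with an estimated correlation. Of 41 mitosis and G2/M genes 28 fell (33 adjusted over the list alone), with the kinase PLK1 at -0.90 ± 0.21, cyclin B1 CCNB1 at -0.64 ± 0.15 and securin PTTG1 at -0.62 ± 0.13. Its adjusted p was 1.80e-09, and adjusted p = 0.551 with an estimated correlation.

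Smaller shifts were called in 5 other lists. In cholesterol and sterol synthesis 16 of 25 genes fell and 1 rose (17 and 2 adjusted over the list alone), among them the enzymes EBP (-0.59 ± 0.11) and SQLE (-0.36 ± 0.06). Camera gave the list adjusted p = 1.12e-05 (adjusted p = 0.30001 with an estimated correlation). In the heat shock list 9 of 18 fell and 2 rose, the same numbers adjusted over the list alone, with the HSP70 genes HSPA1B (-0.88 ± 0.15), HSPA1A (-0.80 ± 0.15) and HSPA8 (-0.39 ± 0.08); HSPA1A and HSPA1B are near-identical and can share reads. The adjusted p was 0.0146 (adjusted p = 0.451 with an estimated correlation). In the integrated stress response list 10 of 31 fell and 1 rose (12 and 1 adjusted over the list alone), the named members being the serine and proline synthesis enzymes PHGDH (-0.53 ± 0.12), PYCR1 (-0.40 ± 0.07) and SHMT2 (-0.35 ± 0.08). As a list they had adjusted p = 0.0129 (adjusted p = 0.586 with an estimated correlation). Of 12 lung epithelial and A549 markers 4 rose and none fell, also adjusted over the list alone, including the aldehyde dehydrogenases ALDH3A1 (0.72 ± 0.16) and ALDH1A1 (0.30 ± 0.09) and the keratin KRT19 (0.69 ± 0.18). The list test gave adjusted p = 0.0119 (adjusted p = 0.388 with an estimated correlation). Of 31 extracellular matrix and adhesion genes 8 rose and none fell, also adjusted over the list alone, including the proteoglycans SDC4 (1.03 ± 0.16) and SDC1 (0.52 ± 0.12) and fibronectin FN1 (0.42 ± 0.10). Together, the members had adjusted p = 0.0295 (adjusted p = 0.734 with an estimated correlation). Named after their values were seen, the members that went against their list were PMVK (0.28 ± 0.10) of sterol synthesis, the tRNA synthetase SARS1 (0.30 ± 0.09) and the chaperone genes HSPA4L (0.57 ± 0.21) and AHSA1 (0.22 ± 0.07). The remaining lung marker was the mucin MUC1 (0.46 ± 0.15). The calls of the lung and matrix lists were lost without the title set term (adjusted p = 0.181 and 0.279) and with a term for the run of columns (0.111 and 0.259).

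Other large rises were in smooth muscle actin ACTA2 (2.30 ± 0.33), tropomyosin TPM4 (ENSG00000167460; 2.14 ± 0.12, adjusted p = 1.77e-29, edgeR quasi-likelihood test, Benjamini-Hochberg), and the lipid transporter ABCA12 (1.93 ± 0.33). Next were a gene without a symbol (ENSG00000248583, 1.88 ± 0.29), the p53-inducible mitochondrial protein SPATA18 (1.81 ± 0.27) and the semaphorin receptor PLXNB3 (1.75 ± 0.36). An effect of the control siRNA on TPM4 stays open (last paragraph). ACTA2 stands in the list of fibroblast markers, whose other 2 measured members were not called (list adjusted p = 0.454, and 0.407 for the blood cell markers). After FAM111B and E2F2, large falls were in the kinetochore motor CENPE (-1.24 ± 0.45), the histone chaperone ASF1B (-1.20 ± 0.24), RTKN2 (-1.16 ± 0.24), ATAD5, which unloads the replication clamp (-1.14 ± 0.24), BRCA2, a recombination protein (-1.11 ± 0.31), and the histone variant H2AX (-1.11 ± 0.19). MYC, a transcription factor of growth, was at -0.13 ± 0.10 (adjusted p = 0.304). Fitted within the title sets alone, fewer genes were called, 980 higher and 875 lower in the numbered and 1153 and 933 in the other titles. CENPE was then at 0.31 in the latter, and FAM111B, E2F2, RTKN2, ATAD5, BRCA2, CCNE2, FN1, ALDH1A1 and HSPA1B were no longer called there. In the numbered titles alone BRCA2, SQLE, SHMT2, PHGDH, ALDH3A1, KRT19 and SDC1 were not called, and BRCA2, CENPE and KRT19 also lost their calls without the set term.

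Footprints of most p53 targets rose and those of most replication, histone and mitosis genes fell, but these list calls too were lost with an estimated correlation. Footprints on BTG2 rose by 3.07 ± 0.45, on MDM2 by 2.05 ± 0.38 and on CDKN1A by 1.79 ± 0.35 (adjusted p = 7.29e-08, 2.03e-05 and 3.33e-05, edgeR quasi-likelihood test, Benjamini-Hochberg; 91 against 11 libraries), and those on CCNE2 fell by 1.53 ± 0.29. In all, 1678 of 12793 genes rose and 1719 fell. Of the 12480 genes tested in both assays, 1153 were called higher in both, where independent lists would share 232, and 1129 lower in both, where independent lists would share 287. Only 2 genes were called in opposite directions, SENP3-EIF4A1 (0.25 in RNA-seq, -0.29 in Ribo-seq) and the transposase-derived gene JRK (-0.28, 0.42), named after their values were seen. The fold changes correlated with r = 0.854 across genes; both assays used the same lysates, controls included.

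Among footprints of the 35 p53 targets, 27 rose and none fell (29 adjusted over the list alone), with FDXR at 2.02 ± 0.30, XPC at 1.76 ± 0.19 and BBC3 at 1.72 ± 0.22 (list adjusted p = 1.41e-17; adjusted p = 0.174 with an estimated correlation). Footprints fell on 37 of 43 DNA replication and G1/S genes (41 adjusted over the list alone), including the helicase subunit MCM4 (-0.997 ± 0.213) and FEN1 (-0.99 ± 0.21). For the list, camera gave adjusted p = 2.96e-15 (adjusted p = 0.380 with an estimated correlation). They fell on 34 of 41 mitosis genes (38 adjusted over the list alone), including the checkpoint protein MAD2L1 (-1.05 ± 0.21), CCNB1 (-0.80 ± 0.16) and PTTG1 (-0.73 ± 0.14). Camera gave the list adjusted p = 3.21e-14 (adjusted p = 0.424 with an estimated correlation). They fell on 29 of 39 histone genes (34 adjusted over the list alone), including H4C13 (-0.89 ± 0.18), H3C1 (-0.87 ± 0.20) and H3C11 (-0.85 ± 0.20). As a list they had adjusted p = 5.00e-13 (adjusted p = 0.434 with an estimated correlation). In cholesterol synthesis 16 of 25 fell and 2 rose (18 and 2 adjusted over the list alone), among them the enzymes SQLE (-0.55 ± 0.07) and EBP (-0.67 ± 0.11). The list test gave adjusted p = 8.30e-08 (adjusted p = 0.168 with an estimated correlation). In the heat shock list 10 of 18 fell and 1 rose (12 and 1 adjusted over the list alone), with HSPA1A (-0.84 ± 0.16), HSPA8 (-0.60 ± 0.08) and the co-chaperone STIP1 (-0.36 ± 0.07) named. This list had adjusted p = 0.000151 (adjusted p = 0.178 with an estimated correlation). In the integrated stress response list 11 of 31 fell and 3 rose (12 and 3 adjusted over the list alone), among them the tRNA exporter XPOT (-0.67 ± 0.11), the folate enzyme MTHFD2 (-0.59 ± 0.11) and asparagine synthetase ASNS (-0.52 ± 0.10). Together, the members had adjusted p = 0.0119 (adjusted p = 0.496 with an estimated correlation). Of 12 lung markers 4 rose, also adjusted over the list alone, including KRT19 (0.83 ± 0.18), ALDH3A1 (0.82 ± 0.16) and ALDH1A1 (0.24 ± 0.09). For the list, camera gave adjusted p = 0.00611 (adjusted p = 0.241 with an estimated correlation, and 0.0963 without the set term). Of 13 mitochondrially encoded genes 3 rose, also adjusted over the list alone, the cytochrome oxidase subunits MT-CO2 (0.41 ± 0.14), MT-CO1 (0.39 ± 0.14) and MT-CO3 (0.38 ± 0.14). Camera gave the list adjusted p = 0.0131 (adjusted p = 0.717 with an estimated correlation). Named after their values were seen, the members that went against their list were PMVK (0.32 ± 0.10), TM7SF2 (0.65 ± 0.26), HSPA4L (0.68 ± 0.19), TRIB3 (0.66 ± 0.15), DDIT4 (0.62 ± 0.14) and SARS1 (0.40 ± 0.09). The remaining lung marker was MUC1 (1.28 ± 0.48). The matrix and adhesion list, called in RNA-seq, was not called in Ribo-seq (adjusted p = 0.151), and the mitochondrially encoded list was not called in RNA-seq (adjusted p = 0.416). Each cytochrome oxidase gene lost its call when control 20_2, 20_1, 21_1 or 21_2 was left out, and MT-CO3 was at -0.00843 in the unnumbered titles alone.

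Other large footprint rises were on the axonemal dynein DNAI3 (3.08 ± 0.52), the zinc finger genes ZSCAN29 (3.04 ± 0.24) and ZNF845 (2.45 ± 0.22), the lipid transfer protein OSBPL5 (2.47 ± 0.25), SPATA18 (2.07 ± 0.34) and the transcription factor FOXP4 (2.06 ± 0.17). Large falls were on FAM111B (-1.54 ± 0.33), the DNA repair genes FANCB (-1.32 ± 0.24), EXO1 (-1.28 ± 0.28), XRCC3 (-1.15 ± 0.20) and MMS22L (-1.11 ± 0.20), the mitotic kinase MASTL (-1.19 ± 0.25) and the mitotic inhibitor FBXO5 (-1.10 ± 0.27). MYC was at 0.01 ± 0.11 (adjusted p = 0.972, edgeR quasi-likelihood test, Benjamini-Hochberg), and below 0 under several alternatives. In the unnumbered titles alone, 496 genes were higher and 211 lower, and FBXO5, FEN1, HSPA1A and ALDH1A1 were not called; in the numbered titles 1126 were lower, and H3C1 and ALDH1A1 were not called.

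Translation efficiency, the ratio of footprints to mRNA, changed for few genes when knockdowns were pooled. ZSCAN29, a zinc finger protein, rose by 2.11 ± 0.21 (lysate-blocked 2.31), and HEXIM1, the inhibitor of the elongation kinase P-TEFb, by 1.01 ± 0.14 (lysate-blocked 1.02; adjusted p = 8.73e-16 and 7.60e-08 for the unblocked values, edgeR quasi-likelihood interaction test, Benjamini-Hochberg; 91 knockdown and 11 control lysates). In all, 54 of 12480 genes rose and 3 fell. Because RNA-seq and Ribo-seq came from one lysate, per-lysate ratios were also tested with limma, which called 222 higher and 114 lower and kept 51 of the 54 and 2 of the 3. Counts moved to 35 higher without control 7 or 9, to 1 lower without control 21_1, 21_2, 7 or 9, to 28 and 1 with libraries of one target summed, to 24 and 1 without the title set term, and to 86 and 29 with no low-count filter. The other named rises were in the zinc finger genes ZNF845 (1.70 ± 0.27, lysate-blocked 1.69), ZNF84 (1.44 ± 0.19, 1.37), ZNF267 (1.02 ± 0.24, 0.92) and ZNF182 (1.00 ± 0.22, 1.11), the ubiquitin ligase subunit FBXW7 (1.44 ± 0.35, 1.13) and OSBPL5 (1.29 ± 0.25, 1.45). The named falls were SENP3-EIF4A1 (-0.54 ± 0.12, -0.56), a read-through gene that shares reads with EIF4A1, and ENSG00000258790 (-0.48 ± 0.13, -0.50), which has no symbol. The last of the 3, PGAM1 (-1.35 ± 0.36), a glycolytic enzyme, lies under the expression floor for named genes and is named after its value was seen. Within the numbered titles 17 genes were higher and none lower, and within the others 5 and none, out of 706 and 259 genes at an unadjusted p under 0.05. Of the named genes ZSCAN29, ZNF84 and HEXIM1 kept their calls in every alternative, ZNF845 lost its call in the numbered titles, and the others lost theirs in both sets.

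No member of a list reached the threshold by the interaction test among the 6 lists that camera called in translation efficiency. DNA replication and G1/S genes had a mean of -0.13 (43 genes; adjusted p = 4.17e-07, and adjusted p = 0.0879 with an estimated correlation) and mitosis genes -0.13 (41 genes; adjusted p = 1.03e-06, and adjusted p = 0.279 with an estimated correlation). Immediate early genes had a mean of 0.20 (21 genes, 2 higher adjusted over the list alone; adjusted p = 7.47e-07, and adjusted p = 0.168 with an estimated correlation). For p53 targets the mean was 0.11 (35 genes; adjusted p = 0.000414, and adjusted p = 0.0752 with an estimated correlation). The proteasome list was at -0.06 (31 genes; adjusted p = 0.0119, and adjusted p = 0.659 with an estimated correlation) and the heat shock list at -0.07 (18 genes; adjusted p = 0.0272, and adjusted p = 0.380 with an estimated correlation). Both lost their calls without the title set term (adjusted p = 0.677 and 0.116), the proteasome list also with the run of columns (0.448). Adjusted over the list alone, no member of these lists was called except the 2 immediate early genes. CDKN1A, MDM2 and MYC were not called (0.25 ± 0.43, 0.69 ± 0.42 and 0.14 ± 0.15, adjusted p = 0.999 each, edgeR quasi-likelihood test, Benjamini-Hochberg); MDM2 was called in the lysate-blocked test (0.50, limma adjusted p = 0.00538).

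RPL5 and RPL11, large-subunit proteins that bind and inhibit MDM2, were examined for the p53 target genes. Their knockdowns had among the lowest p53 responses of the 75 targets. In RNA-seq the mean log2 ratio over the p53 list was 0.03 for RPL5 and 0.01 for RPL11, the 6th and 4th lowest of 75, against a median of 0.87 (range -0.33 to 1.87) and a control SD of 0.0855. In Ribo-seq the means were 0.07 and -0.08, the 5th and 2nd lowest. Each rests on 1 library, so no test was made; the targeted mRNA was at 8.57% of control for RPL5 and 5.11% for RPL11. The lowest value belonged to RPS27L (-0.33), itself a p53 target gene, and RPS15 (-0.08), RPL22 (-0.05) and RPL29 (0.02) also lay below RPL5. In all, 65 of 75 targets lay above every control for p53 targets, and 63 lay below every control for DNA replication and G1/S genes.

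Targets with higher p53 target mRNAs had lower DNA replication and G1/S mRNAs (Pearson r = -0.895, Spearman rho = -0.902, n = 75; permutation p = 1e-05 each, the smallest they can give; adjusted p = 3.00e-05 over 12 relations). Without the 2 most distant targets r was -0.884, within the 16 targets of the numbered titles -0.790 (permutation p = 0.000190) and within the 59 others -0.915 (permutation p = 1e-05). In Ribo-seq r was -0.881 (rho = -0.891), and -0.798 and -0.900 within the sets. All ratios share the control libraries, which add the same offset to every target of a set.

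**Figure D2:**
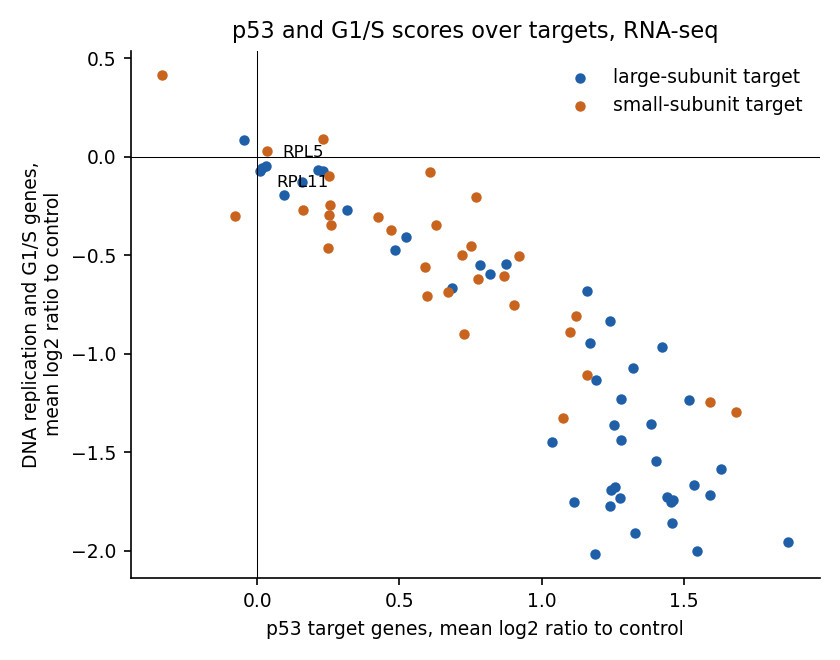
Mean log2 ratio to control over p53 target genes (horizontal) and over DNA replication and G1/S genes (vertical) in RNA-seq, 1 point per target, large-subunit targets in blue and small-subunit targets in orange. The points fall along a line with r = -0.895, and RPL5 (0.03) and RPL11 (0.01) lie near 0 on the horizontal axis.

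In translation efficiency, the lists that differed most between large- and small-subunit knockdowns were mRNAs of the translation machinery. Many of these carry a 5' terminal oligopyrimidine (TOP) motif, through which growth signals control their translation. Their translation efficiency was lower in large-subunit knockdowns. EEF1A1, which delivers tRNA to the ribosome, differed by -1.53 ± 0.12 (large minus small, log2 ± SE; lysate-blocked -1.45). EEF1G, a subunit of its exchange factor, differed by -1.34 ± 0.09 (lysate-blocked -1.35), and EIF4B, an initiation factor, by -1.33 ± 0.09 (lysate-blocked -1.35; adjusted p = 3.84e-25, 3.58e-33 and 6.61e-33 for the unblocked values, edgeR quasi-likelihood interaction test, Benjamini-Hochberg). In all, 144 of 12480 genes were higher and 303 lower in large-subunit knockdowns. The lysate-blocked test called 1019 and 987, and kept 143 of the 144 and 300 of the 303.

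Of 47 large-subunit ribosomal protein genes, 39 had lower translation efficiency, 8 were not called and none was higher (42 lower and 1 higher adjusted over the list alone). They include RPL13A (-1.44 ± 0.13, lysate-blocked -1.46), RPL27A (-1.27 ± 0.10, -1.25) and RPL10 (-1.26 ± 0.13, -1.18); RPL28 (-1.29 ± 0.14, -1.28) was also among the largest falls. Of 30 small-subunit ribosomal protein genes 21 were lower and none higher (26 lower adjusted over the list alone), including RPS4X (-1.29 ± 0.13, lysate-blocked -1.26), RPS6 (-1.26 ± 0.11, -1.38) and RPS19 (-1.10 ± 0.13, -1.04). Of 21 other TOP mRNAs 19 were lower and 1 higher, also adjusted over the list alone; the latter, the poly(A)-binding protein PABPC1 (0.40 ± 0.08), is named after its value was seen. The lower ones include EEF1B2 (-1.27 ± 0.07, lysate-blocked -1.28) and EIF3L (-1.03 ± 0.06, -1.03). The list means were -0.70, -0.72 and -0.73 (camera adjusted p = 7.42e-76, 1.11e-58 and 1.46e-50), and all 3 calls held with an estimated correlation (adjusted p = 7.52e-06, 9.43e-06 and 7.82e-07). Ribosomal protein genes have many pseudogene copies that can share reads. Among other genes, RNF10, a ubiquitin ligase that acts on small-subunit proteins, was higher by 1.49 ± 0.11 (lysate-blocked 1.4998). Next were GON7 (0.70 ± 0.16, 0.66), YBX1, an mRNA-binding protein (0.65 ± 0.10, 0.67), the cytochrome oxidase assembly factor COX20 (0.65 ± 0.17, 0.68) and BOD1 (0.65 ± 0.13, 0.63). The others were the elongin subunit ELOA (0.64 ± 0.13, 0.65), PDCD5 (0.63 ± 0.15, 0.60) and DUS1L, a tRNA dihydrouridine synthase (0.61 ± 0.16, 0.66), while IBTK was lower (-1.28 ± 0.14, -1.34). The histone list was called higher at 0.12 (35 genes; adjusted p = 8.78e-06, and adjusted p = 0.454 with an estimated correlation), although its only called member, H3C8, was lower (-1.74 ± 0.37, lysate-blocked -1.47; 1 higher and 1 lower adjusted over the list alone). CDKN1A, MDM2 and MYC were not called (-0.12 ± 0.29, 0.24 ± 0.26 and 0.02 ± 0.10). Counts moved to 517 higher and 504 lower without the title set term, to 237 and 569 with no low-count filter, and to 71 higher with libraries of one target summed. Within the numbered titles 21 genes were higher and 84 lower, and in the other titles 63 were higher; GON7, ELOA, PDCD5 and DUS1L lost their calls in the former, and COX20 and DUS1L in the latter.

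Per target, the mean log2 ratio of translation efficiency over the other TOP mRNAs was -0.45 ± 0.21 (SD) in the 44 large-subunit and 0.26 ± 0.21 in the 31 small-subunit knockdowns. The difference of -0.71 had permutation p = 1e-05, the smallest they can give (adjusted p = 2.84e-05 over 54 comparisons), and was -0.77 within the numbered titles (exact permutation p = 0.000549, the smallest it can give) and -0.71 within the others (permutation p = 1e-05). All 44 large-subunit targets were below 0, as were 4 of the 31 small-subunit targets. The control libraries had an SD of 0.113. In mRNA amounts the same genes went the other way, at 0.19 ± 0.12 against -0.23 ± 0.13, and in footprints they were at -0.22 ± 0.15 against 0.05 ± 0.15 (permutation p = 1e-05 each, the smallest they can give).

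**Figure D3:**
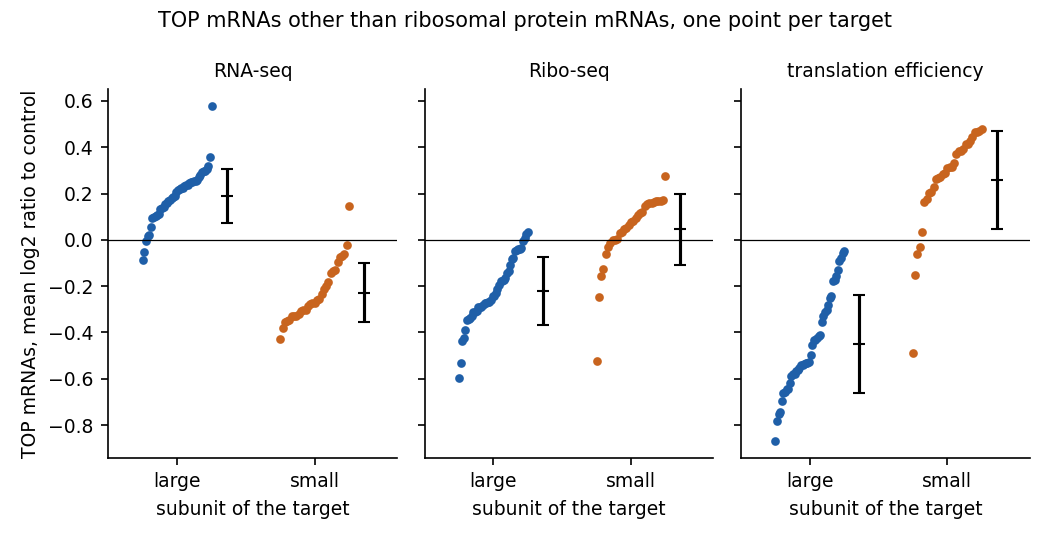
Mean log2 ratio to control over TOP mRNAs other than ribosomal protein mRNAs in RNA-seq, Ribo-seq and translation efficiency, 1 point per target, sorted within large-subunit (blue, n = 44) and small-subunit (orange, n = 31) targets, with the mean and SD as black bars. In translation efficiency all 44 large-subunit points lie below 0 and 4 of the 31 small-subunit points do.

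In mRNA amounts, 2363 of 15526 genes were higher and 2546 lower in large- than in small-subunit knockdowns. EIF4B was higher by 1.14 ± 0.06, the stress transcription factor ATF4 by 0.93 ± 0.06 and the cytokine IL6 by 1.25 ± 0.19 (adjusted p = 7.24e-32, 2.71e-26 and 7.58e-08, edgeR quasi-likelihood test, Benjamini-Hochberg), and the histone H2AC16 was lower (-1.01 ± 0.17). Of 23 other TOP mRNAs 20 were higher and none lower, also adjusted over the list alone, with the elongation factor EEF2 at 0.83 ± 0.06 and EIF3L at 0.70 ± 0.04 (list mean 0.46, adjusted p = 8.30e-36, and adjusted p = 2.73e-06 with an estimated correlation). Of 32 small-subunit ribosomal protein mRNAs 23 were higher and none lower (26 adjusted over the list alone), including RPS9 (0.73 ± 0.10), RPS4X (0.56 ± 0.09) and RPS3A (0.49 ± 0.09), with adjusted p = 8.58e-10 (adjusted p = 6.56e-05 with an estimated correlation). Each of these is itself knocked down in a small-subunit library, and the call held with those values set aside, with the mean at 0.26 in place of 0.39. Of 47 large-subunit ribosomal protein mRNAs 27 were higher (32 adjusted over the list alone), including RPL13A (0.81 ± 0.09), RPL5 (0.50 ± 0.07) and RPL27A (0.40 ± 0.05). As a list they had adjusted p = 0.000231 (adjusted p = 0.120 with an estimated correlation).

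Proliferation genes were lower in large-subunit knockdowns. Of 37 histone genes 36 were lower and 1 higher, also adjusted over the list alone (adjusted p = 3.57e-28; adjusted p = 0.168 with an estimated correlation), among them H2BC21 (-0.84 ± 0.13), H3C11 (-0.84 ± 0.13) and H4C5 (-0.67 ± 0.10). The histone genes H2AC13 (-0.87 ± 0.15), H3C13 (-0.86 ± 0.15) and H1-5 (-0.87 ± 0.18) were among the largest falls. Of 44 DNA replication genes 37 were lower (41 adjusted over the list alone; adjusted p = 4.21e-18, and adjusted p = 0.295 with an estimated correlation), including the chromatin assembly subunits CHAF1A (-0.73 ± 0.15) and CHAF1B (-0.64 ± 0.13) and the polymerase POLA1 (-0.47 ± 0.09). Of 41 mitosis genes 37 were lower (38 adjusted over the list alone; adjusted p = 1.02e-16, and adjusted p = 0.295 with an estimated correlation), including the transcription factor FOXM1 (-0.66 ± 0.12), the kinesin KIF4A (-0.61 ± 0.12) and the phosphatase CDC25B (-0.38 ± 0.07). The histone H3C8 was higher (0.44 ± 0.17), named after its value was seen. The sterol list was lower, with 9 of 25 lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0242; adjusted p = 0.692 with an estimated correlation), with MVK (-0.45 ± 0.09), ACAT2 (-0.33 ± 0.06) and DHCR7 (-0.31 ± 0.07).

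The NF-kB, integrated stress response, immediate early and unfolded protein response lists were higher in large-subunit knockdowns, but not called with an estimated correlation. Heat shock genes (1 higher and 5 lower of 18, adjusted p = 0.464) and interferon response genes (adjusted p = 0.386) were not called. Of 21 NF-kB and cytokine genes 17 were higher (18 adjusted over the list alone; adjusted p = 6.20e-11, and adjusted p = 0.120 with an estimated correlation), with the chemokine CXCL1 at 0.66 ± 0.09 and the signalling kinase IRAK2 at 0.64 ± 0.09. Small-subunit knockdowns were at -0.33 ± 0.33 (SD) and large at 0.02 ± 0.32 against control (SD 0.33), or -0.24 and 0.52 in numbered titles. Of 31 integrated stress response genes 14 were higher, also adjusted over the list alone (adjusted p = 1.38e-06; adjusted p = 0.144 with an estimated correlation), including the phosphatase subunit PPP1R15A (0.64 ± 0.07) and the transporter SLC3A2 (0.33 ± 0.05). Of 22 immediate early genes 14 were higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 1.75e-06, and adjusted p = 0.120 with an estimated correlation), including CCN1 (0.60 ± 0.09) and the phosphatases DUSP5 (0.51 ± 0.08) and DUSP1 (0.40 ± 0.05). JUND was lower (-0.25 ± 0.09, named after its value was seen). Of 23 genes of the unfolded protein response 14 were higher (17 adjusted over the list alone; adjusted p = 8.99e-06, and adjusted p = 0.276 with an estimated correlation), including the chaperones CALR (0.40 ± 0.07) and HSPA5 (0.37 ± 0.07) and HERPUD1 (0.36 ± 0.07). Of 31 matrix and adhesion genes 18 were higher, also adjusted over the list alone (adjusted p = 5.89e-05; adjusted p = 0.424 with an estimated correlation), including the integrins ITGA2 (0.75 ± 0.14) and ITGA3 (0.61 ± 0.09) and the laminin LAMB3 (0.52 ± 0.09). Of 35 p53 targets 16 were higher (18 adjusted over the list alone; adjusted p = 8.78e-06, and adjusted p = 0.638 with an estimated correlation), with GDF15 at 0.70 ± 0.11 and the death receptors TNFRSF10B and TNFRSF10A at 0.54 ± 0.11 and 0.43 ± 0.09. MDM2 (0.75 ± 0.17) and CDKN1A (0.73 ± 0.21) were higher.

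Per target the p53 mean was 1.05 ± 0.54 (SD) in large- and 0.68 ± 0.46 in small-subunit knockdowns, a difference of 0.37 (permutation p = 0.00241, adjusted p = 0.00394). It was 0.13 within the numbered titles (exact permutation p = 0.641) and 0.38 within the others (permutation p = 0.0109). Among smaller lists called higher was lysosome and autophagy (8 of 30 higher, 1 lower, also adjusted over the list alone; adjusted p = 0.0203, and adjusted p = 0.586 with an estimated correlation), with the cholesterol transporter NPC1 (0.34 ± 0.07) and the autophagy receptor SQSTM1 (0.34 ± 0.06) higher and the transcription factor TFEB lower (-0.65 ± 0.08). Translation factors were higher (7 of 32, also adjusted over the list alone; adjusted p = 0.0214, and adjusted p = 0.467 with an estimated correlation), with EIF1 (0.57 ± 0.04), EIF3D (0.28 ± 0.05) and EIF4A1 (0.21 ± 0.05). So were NRF2 targets (5 of 24, also adjusted over the list alone; adjusted p = 0.0219, and adjusted p = 0.659 with an estimated correlation), with thioredoxin reductase TXNRD1 (0.45 ± 0.08), the cystine transporter SLC7A11 (0.39 ± 0.11) and ABCC2 (0.31 ± 0.06). TXN (0.15 ± 0.05) and TKT (0.17 ± 0.06) are named after their values were seen. The remaining large differences were in the snoRNA host gene SNHG5 (0.96 ± 0.06), CXCL5 (0.94 ± 0.15), the lipid transporter ABCA1 (0.94 ± 0.13), the ribosome biogenesis factor NOP53 (0.92 ± 0.06), CITED2 (0.89 ± 0.09) and the pseudogene RPL13AP5, which can share reads with RPL13A (0.91 ± 0.19). The lower ones were TMEM37 (-0.96 ± 0.14), SAMD11 (-0.91 ± 0.14), CENPE (-0.89 ± 0.30) and the kinetochore gene SKA1 (-0.87 ± 0.16). MYC was at 0.20 ± 0.06 (adjusted p = 0.0107, edgeR quasi-likelihood test, Benjamini-Hochberg) and at -0.00399 without the title set term. Within the numbered titles 1047 genes were higher and 1130 lower, and CDKN1A, MDM2, CENPE, CHAF1A, POLA1, NPC1, SQSTM1, SLC7A11 and RPL13AP5 were not called there. HERPUD1 and MYC were not called in the other titles, and CENPE, CALR, EIF3D, EIF4A1, LAMB3 and SQSTM1 lost their calls without the set term. Of the lists, matrix and adhesion (adjusted p = 0.649), large-subunit ribosomal proteins (0.05996), lysosome and autophagy (0.278), translation factors (0.0957), NRF2 targets (0.126) and sterol synthesis (0.0603) lost theirs without it. The lysosome list also did with the run of columns (0.169).

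In footprints, 1381 of 12793 genes were higher and 1426 lower in large- than in small-subunit knockdowns. RNF10 was higher by 1.59 ± 0.09 and IBTK, an inhibitor of a tyrosine kinase, was at -1.20 ± 0.08 (adjusted p = 2.98e-28 and 9.81e-23, edgeR quasi-likelihood test, Benjamini-Hochberg). Footprints were lower on 37 of 47 large-subunit ribosomal protein mRNAs and higher on 3 (41 and 4 adjusted over the list alone), including RPL28 (-0.96 ± 0.10), RPLP1 (-0.93 ± 0.16), RPL27A (-0.88 ± 0.08), RPLP0 (-0.82 ± 0.08) and RPL27 (-0.45 ± 0.04). RPL17 (0.53 ± 0.13), RPL41 (0.31 ± 0.09) and RPL14 (0.23 ± 0.09) were higher. They were lower on 20 of 30 small-subunit ribosomal protein mRNAs (21 adjusted over the list alone), including RPS6 (-0.88 ± 0.06), RPS19 (-0.80 ± 0.10) and RPS21 (-0.68 ± 0.08). Of 21 other TOP mRNAs 14 were lower, also adjusted over the list alone, including EEF1B2 (-0.92 ± 0.07), EEF1G (-0.81 ± 0.07) and EEF1D (-0.56 ± 0.06), and 2 higher, EIF4A2 (0.54 ± 0.07) and PABPC1 (0.48 ± 0.05). The genes that were higher are named after their values were seen. The 3 list means were -0.53, -0.33 and -0.25 (adjusted p = 1.55e-27, 2.93e-07 and 4.24e-10), and the calls held with an estimated correlation (adjusted p = 7.82e-07, 0.00562 and 0.0407). Both assays called 722 genes higher, where independent lists would share 198, and 840 lower, where they would share 247, while 98 genes were called in opposite directions; fold changes correlated with r = 0.670 across genes.

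The other footprint lists followed their mRNAs in direction. Histones were lower (33 of 39 lower, 36 adjusted over the list alone; adjusted p = 3.10e-23, and adjusted p = 0.217 with an estimated correlation), with H3C4 (-1.30 ± 0.25), H4C1 (-0.69 ± 0.15) and H4C5 (-0.61 ± 0.10). Mitosis genes were lower (30 of 41, 37 adjusted over the list alone; adjusted p = 2.80e-20, and adjusted p = 0.276 with an estimated correlation), with KIF11 (-0.66 ± 0.16), CDC25C (-0.65 ± 0.16) and KIF4A (-0.53 ± 0.13). So were DNA replication genes (33 of 43, 36 adjusted over the list alone; adjusted p = 1.22e-19, and adjusted p = 0.273 with an estimated correlation), with MCM3 (-0.71 ± 0.15), POLD1 (-0.49 ± 0.10) and RRM1 (-0.41 ± 0.09). Sterol synthesis was lower too (9 of 25 lower and 2 higher, 10 and 2 adjusted over the list alone; adjusted p = 0.0479, and adjusted p = 0.725 with an estimated correlation), with MVK (-0.46 ± 0.09), MVD (-0.31 ± 0.08) and FDPS (-0.22 ± 0.04). NF-kB and cytokine genes were higher (17 of 22, 18 adjusted over the list alone; adjusted p = 9.98e-11, and adjusted p = 0.120 with an estimated correlation), with the chemokines CXCL3 (1.18 ± 0.20) and CXCL5 (1.03 ± 0.17) and the adaptor TRAF1 (1.07 ± 0.18). Genes of the unfolded protein response were higher (15 of 23, 18 adjusted over the list alone; adjusted p = 1.51e-08, and adjusted p = 0.168 with an estimated correlation), with CALR (0.42 ± 0.07), HYOU1 (0.38 ± 0.08) and HSP90B1 (0.33 ± 0.06). Matrix and adhesion genes were higher (17 of 32 with 1 lower, also adjusted over the list alone; adjusted p = 2.01e-07, and adjusted p = 0.218 with an estimated correlation), with ITGA2 (0.87 ± 0.13), ITGA3 (0.54 ± 0.09) and LAMA3 (0.38 ± 0.05). The p53 targets were higher (14 of 35, 19 adjusted over the list alone; adjusted p = 4.68e-06, and adjusted p = 0.586 with an estimated correlation), with MDM2 (0.99 ± 0.21), TRIAP1 (0.65 ± 0.12), GDF15 (0.63 ± 0.11) and CDKN1A (0.61 ± 0.21). So were integrated stress response genes (10 of 31, 11 adjusted over the list alone; adjusted p = 5.01e-06, and adjusted p = 0.120 with an estimated correlation), with STC2 (0.62 ± 0.11), PPP1R15A (0.58 ± 0.11) and SLC3A2 (0.36 ± 0.06). Immediate early genes were higher (8 of 21 with 1 lower, 10 and 1 adjusted over the list alone; adjusted p = 2.43e-05, and adjusted p = 0.218 with an estimated correlation), with DUSP5 (0.68 ± 0.09), IER3 (0.62 ± 0.10) and DUSP1 (0.47 ± 0.08). Named after their values were seen, SC5D of the sterol list was higher (0.25 ± 0.08), and JUND (-0.32 ± 0.12) and THBS1 of the matrix list (-0.29 ± 0.10) were lower.

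Lysosome and autophagy footprints had a weaker call (11 of 30 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.000189, and adjusted p = 0.186 with an estimated correlation), with TFEB lower (-0.57 ± 0.16, named after its value was seen) and NPC1 (0.39 ± 0.07), the protease CTSB (0.31 ± 0.05) and PSAP (0.25 ± 0.04). The NRF2 targets had one too (7 of 24 higher, 7 higher and 1 lower adjusted over the list alone; adjusted p = 0.0215, and adjusted p = 0.638 with an estimated correlation), with SLC7A11 (0.41 ± 0.09), TXNRD1 (0.36 ± 0.08) and ferritin FTH1 (0.39 ± 0.10, but -0.07 without the title set term). Interferon response genes (8 of 33 higher, also adjusted over the list alone; adjusted p = 0.0295, and adjusted p = 0.388 with an estimated correlation) included OASL (0.86 ± 0.20), IFIT5 (0.23 ± 0.07) and IRF1 (0.22 ± 0.07). Ribosome biogenesis (11 of 60 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.0401, and adjusted p = 0.777 with an estimated correlation) included NOP10 (0.36 ± 0.07) and PNO1 (0.27 ± 0.06), while fibrillarin FBL was lower (-0.26 ± 0.05). Without the title set term the calls of matrix and adhesion (adjusted p = 0.0559), immediate early (0.0745), interferon (0.10004), ribosome biogenesis (0.375) and sterol lists (0.361) were lost. With libraries of one target averaged ribosome biogenesis (0.151) and sterol synthesis (0.0751) were not called, with the run of columns ribosome biogenesis (0.0516) and interferon response (0.0577) were not, and with the targeted genes' own values set aside sterol synthesis (0.0544) was not. Among other genes, the monocarboxylate transporter SLC16A6 (1.04 ± 0.16), the polyamine enzyme SMOX (1.03 ± 0.08) and SPTLC2 of sphingolipid synthesis (0.96 ± 0.07) were higher. Other large falls were in EBF4 (-1.51 ± 0.30), FEZF2 (-1.14 ± 0.34), LRRC45 (-1.12 ± 0.17), RMI2 (-1.09 ± 0.23) and H3C13 (-0.93 ± 0.18). MYC was at 0.23 ± 0.08 (adjusted p = 0.0218, edgeR quasi-likelihood test, Benjamini-Hochberg) and not called in the unnumbered titles or without the set term. Without the set term 2357 genes were higher and 2407 lower, and within the unnumbered titles 701 and 708. In the numbered titles alone 881 were higher, and CDKN1A, TRIAP1, SLC7A11, TXNRD1, FTH1, NPC1, CTSB, PSAP, OASL, IFIT5, IRF1, PNO1, FBL, POLD1, MVD, RMI2 and FEZF2 were not called there.

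For the 16 targets with 2 libraries, each knockdown was compared with the 6 controls of the numbered titles. The number of genes called differed between targets, with a median of 3945.5 in RNA-seq, from 1743 for RPL29 to 5661 for RPS15, and of 3530.5 in Ribo-seq, from 1473 for RPL29 to 4830 for RPS3. In translation efficiency the median was 190 (176 in the lysate-blocked test, 405.5 without control 20_2 and 62.5 with the controls split between targets), from 5 for RPL29 to 1298 for RPS12. CDKN1A mRNA rose by 2.14 ± 0.14 for RPL21, 2.02 ± 0.15 for RPL15 and 1.95 ± 0.15 for RPS3 (adjusted p at most 2.18e-11, edgeR quasi-likelihood test, Benjamini-Hochberg; 2 against 6 libraries). MDM2 was highest for RPL21 (2.21 ± 0.28) and lower than control for RPS15 (-1.04 ± 0.33, adjusted p = 0.0165 by the same edgeR test), where its footprints were not called (-0.35 ± 0.21, adjusted p = 0.239). Both RPS15 RNA-seq libraries had few genes detected (22723 and 22880), as had controls 20_1 (22468) and 20_2 (21477). RPS15 ranked 1 of 75 by RNA-seq distance but 51 by Ribo-seq distance, with 2866 genes called in Ribo-seq, so its RNA-seq values are uncertain.

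Some genes changed in most of 16 knockdowns (12 small-subunit). TPM4 mRNA rose in 16 of 16 (mean log2 fold change 2.17 ± 0.32, SD), as did SNX18P12, a pseudogene that can share reads with its parent (1.802 ± 0.521), and the cell cycle kinase CDK14 (1.69 ± 0.34). H2AX (-1.37 ± 0.70), the Notch inhibitor NRARP (-1.26 ± 0.37) and the centromere chaperone HJURP (-0.94 ± 0.71) fell in 16 of 16, HJURP in 10 with no low-count filter. Footprints rose in 16 of 16 on ZSCAN29 (2.84 ± 0.36), OSBPL5 (2.30 ± 0.40) and FOXP4 (2.11 ± 0.47) and fell in 16 of 16 on MASTL (-1.34 ± 0.88), H2AC15 (-1.13 ± 0.84) and H3C10 (-1.07 ± 0.90). Translation efficiency rose in 16 of 16 for HEXIM1 (1.21 ± 0.25), in 14 for BHLHE40, a transcriptional repressor (0.79 ± 0.21), and in 13 for the chromatin regulator ANKRD11 (1.08 ± 0.29). It also rose in 13 for the zinc finger gene ZKSCAN1 (1.06 ± 0.18), named after its value was seen. It fell in 14 for TXNDC5 (-0.50 ± 0.17), in 11 for ELOA (-0.42 ± 0.57) and in 9 for RNF10 (-0.42 ± 0.69). ELOA and RNF10 rose in 1 and 2 and differed by subunit. With all 11 controls BHLHE40 was called in 8 and TXNDC5 in 5, and with split controls TXNDC5 in 8 and RNF10 in 4.

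In at least 12 of the 16 knockdowns 422 mRNAs were higher and 190 lower, against 6.49e-05 and 5.77e-04 genes for independent lists. Unchanged groups simulated against simulated controls, shared by all targets, gave 0 and 0. Splitting the controls between targets gave 304 higher, and lessened the number of lower mRNAs by over 1.5 times. For footprints the numbers were 424 and 272, against 1.44e-04 and 7.93e-04 for independent lists, 0 and 0 in the simulation and 293 and 169 with split controls. For translation efficiency they were 4 and 1, and 2 and 0 with split controls. The simulated value leaves out the effects and the value for independent lists the shared controls, so part of the excess may come from the controls that all 16 comparisons share.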

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

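In this part, the test on TOP mRNAs that hold no targeted gene was chosen only after the result was seen. All 8 values below are differences between large- and small-subunit knockdowns, relative to the same controls, that passed the list test also with an estimated correlation. In mRNA amounts, the mean log2 difference (large minus small) was 0.46 over the other TOP mRNAs and 0.39 over small-subunit ribosomal protein genes (0.26 with targeted genes' own values set aside). In footprints it was -0.53 over large-subunit ribosomal protein genes (-0.44 so set aside), -0.33 over small-subunit ones (-0.45) and -0.25 over the other TOP mRNAs. In translation efficiency it was -0.70, -0.72 and -0.73 over the same 3 lists.

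The lower translation efficiency of TOP mRNAs in large-subunit knockdowns was weighed against 3 technical explanations. The targeted genes' own knockdown is excluded as the whole cause, since the list without targeted genes differed by -0.71 over the 75 targets. The title set is excluded likewise, since the smaller of the differences within the 2 sets was -0.71. Reads shared with pseudogenes are not excluded. The median difference was -0.79 over 65 ribosomal protein genes with a footprint CPM of at least 50 and -0.68 over the other 12. Shared reads can raise the CPM, so this cannot decide. Against control both groups moved, large-subunit knockdowns to -0.45 ± 0.21 (SD; 44 of 44 targets below 0) and small-subunit knockdowns to 0.26 ± 0.21 (4 of 31 below 0), with a control SD of 0.113. How far the counting of reads mapping to several genes adds to either stays open.

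Random splits of the knockdown libraries called fewer genes than the split by subunit. In RNA-seq 1 of 40 splits, the real one, called as many (4909, and 909 in the highest other), and 1 is the least possible. In Ribo-seq it was 1 of 40 (2807, and 75), and in translation efficiency 1 of 40 (447, and 1).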

How the results depend on the processing

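In this part, the alternatives with the run of columns, without control 20_2 per target or for lists, and with split controls were chosen only after the data were seen. Of 7594 values under alternatives for 417 results, 7097 kept their direction and side of the threshold, 398 lost a call or a count by over 1.5 times, 79 gained one, 3 moved by more than their spread and 17 changed sign. Named genes kept their call in 5276 of 5455 values, lost it in 160 and changed sign in 16; called lists kept theirs in 349 of 427 and lost it in 78. Where no construction is named, the cause was not tested. Depth limits what low footprint counts can show.

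Each title set alone has fewer libraries and called fewer genes. Against control, RNA-seq gave 980 higher and 875 lower in the numbered and 1153 and 933 in the unnumbered titles. In that order Ribo-seq gave 1126 lower, then 496 and 211, and translation efficiency 17 and 0, then 5 and 0. Between subunits the counts were 1047 and 1130 in RNA-seq (numbered), 881 higher in Ribo-seq (numbered) and 701 and 708 in Ribo-seq (unnumbered). In translation efficiency they were 21 and 84 (numbered) and 63 higher (unnumbered).

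In translation efficiency against control, the counts (54 higher and 3 lower as reported) were 28 and 1 with libraries of one target summed, 86 and 29 with no low-count filter, 24 and 1 with no title set term, and 35 to 51 and 1 to 4 leaving out each control in turn. Between subunits (144 and 303) they were 71 higher when summed, 237 and 569 with no filter and 517 and 504 with no title set term; in Ribo-seq without that term they were 2357 and 2407.

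The lysate-blocked test, limma on log2 ratios paired as the protocol gives, called more genes in translation efficiency, 222 and 114 against control (224 and 118 with prior count 0.5, 270 and 182 with the run of columns as well). Between subunits the lysate block gave 1019 and 987 (1008 and 976 with prior count 0.5, 1186 and 989 with the run). It changes the test as well as the block, so the cause of the higher counts was not separated.

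The replicate numbers in the titles do not pair libraries. Differences of replicate 1 and 2 correlated between groups with a median r of -0.0658 in RNA-seq, 0.0603 in Ribo-seq and 0.0172 in translation efficiency, and 41.2%, 43.1% and 26.8% of 153 pairs were over 0.1. With the number as a replicate block, 2312 genes were higher and 2692 lower against control in RNA-seq, and 1508 and 1303 in Ribo-seq; between subunits 2428 and 2653, and 1376 and 1442. MYC footprints were then at -0.0575.

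Per target, the median number of calls in translation efficiency (190) was 62.5 with controls split between targets, which leaves fewer controls for each, and 172 to 405.5 over leave-outs, the highest without control 20_2. With an estimated correlation 0 lists were called against control in RNA-seq, 0 in Ribo-seq and 0 in translation efficiency, and 2 and 3 between subunits in RNA-seq and Ribo-seq. Against control, 11 lists were called in translation efficiency with libraries of one target averaged and 13 without control 20_2; between subunits 8 were with no title set term. The difference of the distances from control in RNA-seq was -0.0149 with the median absolute deviation; in Ribo-seq it was 0.000319 that way (permutation p = 0.985), and passed the threshold with all 11 controls (0.0530), a mean CPM of at least 50 (0.0540) and thinning (0.0449). The RPL5 knockdown had 0.19 in Ribo-seq as the median over the p53 list. A pseudocount of 5, which shrinks low values, gave medians of -4.24 and -3.64 for the targeted gene in RNA-seq and Ribo-seq.

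The signs that changed were CENPE in RNA-seq against control (0.31 in the unnumbered titles), MT-CO3 footprints (-0.00843, unnumbered) and MYC, whose values lay near 0. MYC footprints against control were at -0.0681 with the run, -0.00883 summed, -0.0606 with no title set term, -0.16 in the unnumbered titles and -0.0263 to 0.0599 leaving out each control, below 0 without 20_1, 20_2, 21_1 or 21_2. MYC translation efficiency against control was at -0.0303 in the unnumbered titles. Between subunits MYC was at -0.00399 in RNA-seq with no title set term and at -0.0505 in translation efficiency with the run and -0.0482 with the run and the lysate block, and FTH1 footprints at -0.0667 with no title set term.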

Other observations

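In this part, the tests on control 20_2 and the tests on genes chosen in the numbered titles were chosen only after the result was seen. Knockdown of RPL22, a large-subunit protein with the close paralog RPL22L1, gave the highest RPL22L1 level of the 75 targets, at a log2 ratio of 1.68 in RNA-seq and 1.77 in Ribo-seq, where the medians of the other targets were -0.68 and -0.92. Each value is from 1 library. Knockdown of RPL39 had the lowest level of its paralog RPL39L in RNA-seq (-2.68) and the next to lowest in Ribo-seq (-2.05); near-identical copies can share reads, and whether the siRNA also matches RPL39L was not tested. Both pairs were picked after their values were seen. Other pairs showed no such rise in RNA-seq: among the targets, RPL36AL ranked 18 of 75 from the highest in RPL36A knockdown, RPL7L1 33 of 75 in RPL7, RPS27 43 of 74 in RPS27L, RPS27L 62 of 74 in RPS27 and RPL26L1 72 of 75 in RPL26 knockdown.

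Other gene groups were not called between all knockdowns and controls in mRNA amounts. Camera adjusted p was 0.0570 for nuclear oxidative phosphorylation genes (12 higher and 2 lower of 72), 0.181 for the unfolded protein response, 0.280 for fatty acid synthesis, 0.283 for the proteasome, 0.341 and 0.502 for large- and small-subunit ribosomal proteins, 0.345 for NRF2 targets, 0.386 for translation factors, 0.416 for NF-kB genes and 0.416 for mitochondrially encoded genes. It was 0.493 for glycolysis, 0.644 for interferon response, 0.670 for lysosome and autophagy, 0.787 for immediate early genes, 0.795 for mitochondrial ribosomal proteins, 0.861 for ribosome biogenesis and 0.946 for the other TOP mRNAs, whose mean (-0.01) was opposite in sign to the test. The oxidative phosphorylation list was called with DESeq2 size factors (0.0411), libraries of one target averaged (0.00955) and without control 20_2 (4.34e-04), and the mitochondrially encoded list with the run of columns (0.0320).

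Random splits of the libraries called fewer genes than knockdowns against controls. In RNA-seq 1 of 40 splits, the real one, called as many (4745), and 1 is the least possible. The highest other called 2203, which points to a structure of the samples beyond knockdown and control. In Ribo-seq it was 1 of 40 (3397, and 681 in the highest other) and in translation efficiency 1 of 40 (57, and 9).

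Control 20_2 stood apart in RNA-seq, with a distance of 0.983 from the other controls of its title set. Its depth does not account for this, since its total of 40.8 M counts lay within the range of the other controls. A difference of the cells themselves would be expected in both assays of the lysate, but its Ribo-seq distance was 0.220, the lowest of the 11 controls; the bound for this test was reworded after the value was seen. An RNA-seq library made or handled differently stays open. It had the fewest genes detected of the controls (21477), the lowest TMM factor of all RNA-seq libraries (0.849) and 12.99% of counts in its top 10 genes. Few genes were also detected in control 20_1 (22468), one RPS7 library (21110), both RPS15 libraries and one RPS15A library (22784).

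Few genes separated every knockdown from every control. In RNA-seq 4 genes lay above all 11 controls in all 91 knockdown libraries, HABP4, HSDL2, ZSCAN29 and TPM4 (named after their values were seen), and none below; in Ribo-seq 8 lay above, 3 of them the same, and none below. Ribosomal protein loss and an effect of the control siRNA, common to all comparisons, may each account for this and cannot be told apart. Their mean had r = 0.214 with the p53 score over 75 targets (permutation p = 0.0650) and an SD of 0.108 of its mean. The test is void on genes chosen for full separation. In the numbered titles 64 genes lay above all controls (0.00562 by chance if repeats were independent). In the other 59 targets these 64 had r = 0.819 (0.712 to 0.889) and an SD of 0.137 of the mean. Gene by gene, for 63 of them without the p53 list's own member, the median r was 0.154 (quartiles -0.0342 and 0.462), and 34.9% had an SD of at most 1/3 of the mean. Over the same targets r was 0.618 for HSDL2, 0.0667 for HABP4, 0.0553 for TPM4 and -0.0541 for ZSCAN29. The mean thus does not stand for each. Both measures were made after earlier results were seen, so none is preferred.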
